A study of Homo sapiens with 4 samples.

How the data were processed

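Expression was measured on 4 two-colour microarrays of OCI-Ly3, a human diffuse large B-cell lymphoma line of the activated B-cell type. The cells carried a doxycycline-inducible short hairpin RNA against IKKa, the kinase encoded by CHUK. Per the labels, cDNA of doxycycline-treated cells was coupled to Cy5 and cDNA of cells without doxycycline to Cy3 on every array, and no array had the dyes swapped. On 2 arrays neither channel had inhibitor (doxycycline for 2 or 3 days). On the other 2 arrays both channels had the IKKb inhibitor MLN120b at 12.5 uM, for 3 h in the array with 2 days of doxycycline and for 24 h in the array with 3 days. Doxycycline was used at 20 ng/ml.

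The deposited values are log ratios of the channels, 1 per probe and array, read here as log2. The base and the direction of the ratio are not stated in the file. A log10 base would make the range of -5.61 to 7.49 span 13.1 orders of magnitude, so base 2 was taken. The direction, doxycycline over no doxycycline, is the likely one: it follows the usual Cy5 over Cy3 order, and both CHUK probes then lie below 0 on all 4 arrays. The array medians lie between -0.007 and 0, so the deposited log ratios appear to have been centred. The scanner signals were not used here, and background correction, normalization, spot filtering and the reason for empty cells are not given in the sources used here. Signal over background is therefore unknown, and the number of arrays limits the precision.

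Of 15246 probes, 10169 had 1 gene symbol in the platform annotation, 4 had several and 5073 had none. Gene identifiers matched the RefSeq gene table (assembly GRCh38.p14, used only for current names and gene spans) for 10128 probes and did not match for 45, which kept their listed symbol. The arrays held values for 14375 probes (doxycycline 2 days), 12546 (3 days), 12018 (2 days with inhibitor) and 11722 (3 days with inhibitor). A value on all 4 arrays was required, which left 9788 probes, 6796 of them with 1 gene. The probes of a gene were averaged, giving 3589 genes, of which 1866 rested on 1 probe and 1723 on 2 or more. No genomic coordinates are given, because the sources name no genome build for the array.

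One model was fitted with limma 3.58.1 (lmFit, then eBayes, in R 4.3.3) with a mean for each of the 2 groups of 2 arrays. Tests were the mean log ratio without inhibitor against 0, the mean with inhibitor against 0, and the difference of these means. All p-values are two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual degrees of freedom and a prior of 4.98. The 2 arrays of a group are different time points and not repeats of one condition, so the spread behind each p-value includes any change with time. Nothing in the labels says that arrays came from separate cultures, and the p-values measure only the spread between these arrays. Whether arrays share an uninduced RNA is not given in the sources used here. A rule of size, beyond 1.5-fold in one direction on both arrays of a group, was counted beside the test.

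Before the data were examined, 20 gene lists were fixed, together with the tests, the alternatives and the genes to be named. The lists are NF-kB targets, IKK and NF-kB pathway components, STAT3 and cytokine response, ABC and GCB lymphoma markers, B cell identity, plasma cell differentiation, cell cycle, MYC and ribosome biogenesis, ribosomal proteins, apoptosis regulators, p53 targets, interferon response, unfolded protein and amino acid stress response, heat shock, cholesterol synthesis, glycolysis and hypoxia, T cell markers, myeloid markers and housekeeping genes. Each was tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 20 lists of a comparison, and again with an estimated correlation, which in camera also lowers the degrees of freedom to the 2 of the fit, and with fry (statmod 1.5.0 was installed beside limma). With 2 degrees of freedom the test with an estimated correlation has little power, so a call lost in it is not evidence against the list. The named genes are CHUK and, for each comparison, the 10 largest means of each sign among genes past the threshold with the same sign on both arrays, or among all same-sign genes where fewer than 10 pass. They further include the 8 NF-kB targets with the largest absolute difference, up to 4 members of each other list that passes and up to 2 of each that does not, and a fixed set of NF-kB genes and cytokines. Other called list members are named where the text says so.

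Alternatives were median centring, scaling of arrays to equal spread, probes with a value on at least 1 array per group, tests on single probes, doxycycline day as a block, each array left out in turn, a robust prior, an adjusted p under 0.10, the 2 other list tests and a 2-fold rule. The fit was tested on simulated data with 200 of 3589 genes changed. At a log2 change of 1 it recovered 93.5% of them without inhibitor, 96.5% with inhibitor and 54% for the difference, and at 0.5 it recovered 0% in each. A shift of 0.2 in the 52 NF-kB genes gave an unadjusted camera p under 0.05 for the difference in 100% of 100 simulations, against 2% with no shift. These simulations draw genes independently, which real genes are not. A changed gene was given the same change on both arrays, with no change over time. In the data without inhibitor MATR3, at -1.52, was not called (limma adjusted p = 0.0693). The 0 calls there thus do not exclude 2-fold changes. Figures were drawn with matplotlib 3.10.9. No array with a control hairpin, or with doxycycline in cells lacking the hairpin, was analysed here, so effects of the hairpin, of doxycycline and of the dyes stand together in each mean.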

Results

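The series profiled OCI-Ly3 cells on 4 two-colour arrays, each setting cells with doxycycline-induced IKKa hairpin against uninduced cells at the same inhibitor status. OCI-Ly3 is a lymphoma line of the activated B-cell (ABC) type, whose growth depends on NF-kB signalling. IKKa and IKKb are the related kinases of the IkB kinase complex, which releases NF-kB from its inhibitors, and MLN120b blocks IKKb. The series title names the question: whether IKKa compensates in classical NF-kB signalling while IKKb is inhibited. Doxycycline was given for 2 or 3 days without inhibitor (2 arrays), and for 2 days with 3 h of inhibitor or 3 days with 24 h of inhibitor (2 arrays). Values are mean log2 ratios, below 0 where the induced cells were lower in the likely direction of the ratio, over 3589 genes measured on all 4 arrays. Were the direction the other way round, every lower or fallen value here would be higher or risen, and the reverse. SDs are over the 2 time points of a group.

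CHUK, the gene of IKKa and the target of the hairpin, was below 0 on all 4 arrays. That sign was part of the basis for the likely direction of the ratio, so it is no separate check of the knockdown. Its log2 ratio was -0.59 and -0.87 at 2 and 3 days without inhibitor, and -1.30 and -1.01 with inhibitor. The mean was -0.73 ± 0.20 (SD, n = 2) without inhibitor, 1.66-fold lower in that direction, and -1.15 ± 0.20 with inhibitor, 2.23-fold. The limma adjusted p was 0.155 without and 0.013 with inhibitor. The means differed by -0.42 (SE 0.19, adjusted p = 0.989), a difference that did not pass. Both probes of the gene were below 0 on every array.

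The arrays without inhibitor ask what the hairpin did while IKKb was active. Every gene among the 33 beyond 1.5-fold on both arrays was lower in the likely direction of the ratio, and all 33 would be higher were it the other way round. With all probes that had a value on both of these arrays, 3 genes were higher and 34 lower, and as single probes 3 were higher and 124 lower. The lowest were MATR3, a nuclear matrix RNA-binding protein, at -1.52 ± 0.39, ALCAM, a cell adhesion molecule, at -1.51 ± 0.06, and CD2AP, an adaptor of the actin cytoskeleton, at -1.37 ± 0.24. DHX15, an RNA helicase of splicing, stood at -1.29, PARPBP at -1.21, SEL1L and HSP90B1, both of the endoplasmic reticulum, at -1.17, BTN2A2 at -1.15, NMD3, a ribosomal export adaptor, at -1.09 and TUFM, the mitochondrial elongation factor, at -1.08. CD2AP had 3 probes and HSP90B1 2, while the others of these lowest genes rested on 1 probe each. Some of these genes differed by day: DHX15 had -0.75 at 2 and -1.84 at 3 days, PARPBP -0.83 and -1.59, and HSP90B1 -0.60 and -1.74. The largest positive means among genes above 0 on both arrays were smaller and included ABCC2 at 0.64, CD1D at 0.57, FER at 0.57, S1PR1 at 0.52 and GLRX at 0.50. None of these genes passed: limma called 0 of 3589 genes (smallest adjusted p 0.0693), with 400 at an unadjusted p under 0.05, 354 lower and 46 higher, where chance gives 179.

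NF-kB targets without inhibitor had a median of -0.11, with 40 of 52 measured members below 0 and none passing alone over all genes (1 passed when adjusted over the list alone). CCL22, a chemokine gene induced by NF-kB, had the lowest mean at -0.95 ± 0.25 (adjusted p = 0.0882). IRF4, the transcription factor on which ABC lymphoma lines depend, stood at -0.47 and NFKBIA, which encodes the inhibitor IkBa, at -0.29. The list passed camera at an adjusted p of 0.0467, which became 0.627 in the test with an estimated correlation. That test also lowers the degrees of freedom to 2, and for this list the estimate, 0.0038, lay below the preset 0.01, so the loss is not due to correlation among its genes. The call ended when any 1 of the 4 arrays was left out (adjusted p 0.0732 to 0.183), after scaling to equal spread (0.0604) and with the doxycycline day as a block (0.0757).

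Other groups lay further below 0 without inhibitor. Cell cycle genes had a median of -0.23, 30 of 38 below 0 (adjusted p = 0.00104), with MCM4 of the replicative helicase at -0.65 and the mitotic kinase NEK2 at -0.53. Genes of the unfolded protein and amino acid stress response had -0.25, 19 of 20 below 0 (0.00134), with HSP90B1 at -1.17 and CALR at -0.45, both chaperones of the endoplasmic reticulum. MYC and ribosome biogenesis genes had -0.29 (0.00879), with ENO1 at -0.86 and nucleolin, NCL, at -0.61. ABC lymphoma markers had -0.18 (0.0303), with TCF4 at -0.64 and STAT3 at -0.38, and glycolysis genes -0.17 (0.0446), with GPI at -0.57 and ALDOA at -0.54. Housekeeping genes, often used as references, lay on the same side, at -0.29 (0.0131), with ACTB at -0.70 and GAPDH at -0.42. T cell markers (0.06, adjusted p = 0.0303) and germinal-centre (GCB) lymphoma markers (0.08, 0.0464) lay above 0. In these 2 lists 60% and 44.2% of probes lacked a value on 1 or more arrays, against 0% for housekeeping genes. With an estimated correlation the smallest adjusted p of any list was 0.627, so no list call held in that test. The estimated correlation was 0.61 for cell cycle, 0.76 for MYC, 0.39 for unfolded protein and 0.78 for housekeeping genes, far above the preset 0.01. T cell markers, with an estimate of only 0.05, had the same camera adjusted p of 0.627. Whether correlation or the 2 degrees of freedom ended each call cannot be told. Medians were further from 0 at 3 days: -0.12 at 2 and -0.36 at 3 days for cell cycle genes, and -0.10 and -0.37 for MYC genes. No member of any list passed by itself over all genes.

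The limma count of 0 became 140 genes (7 higher, 133 lower) after arrays were scaled to equal spread and 56 with the day as a block. It became 231 without the inhibitor array of 3 h and likewise 231 without that of 24 h, where the spread rests on the remaining group of 2.

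**Figure D1:**
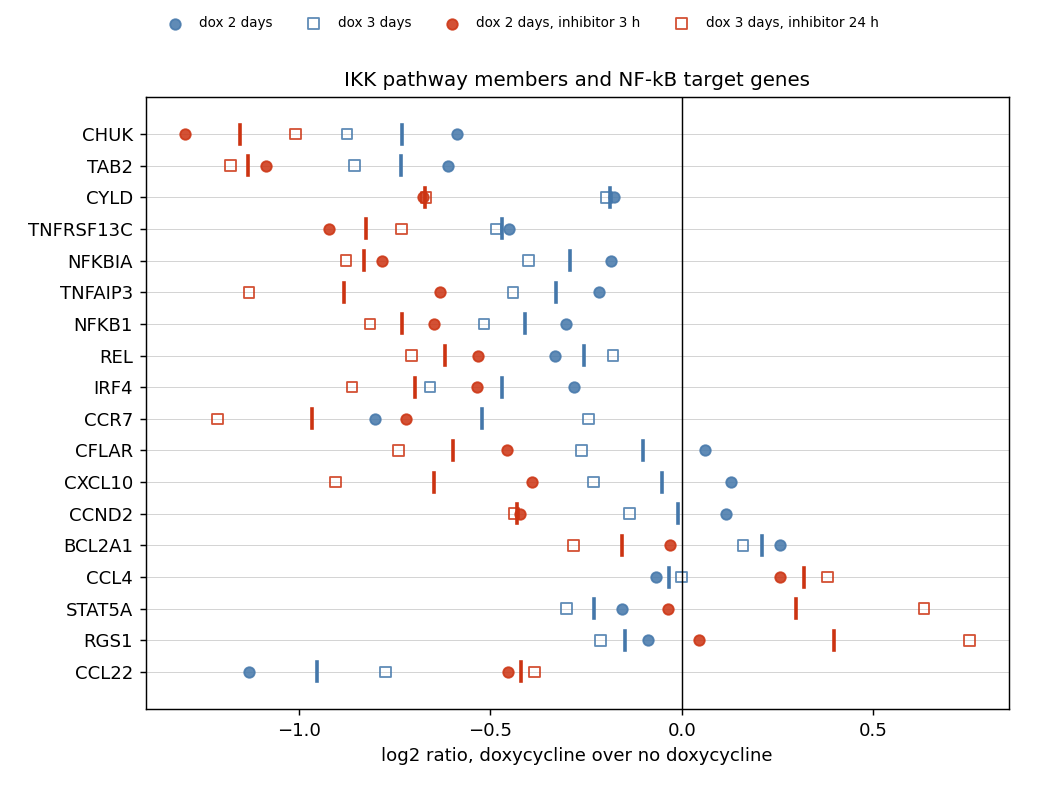
Log2 ratio (horizontal axis, doxycycline over no doxycycline in the likely direction) of CHUK, IKK pathway members and NF-kB target genes on each of the 4 arrays, with circles for 2 days and open squares for 3 days of doxycycline, blue without and red with inhibitor, and vertical bars for the mean of each group of 2 arrays. NFKBIA has group means of -0.29 without and -0.83 with inhibitor, while CCL22 lies the other way round, at -0.95 and -0.42.

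The arrays with MLN120b in both channels ask what the hairpin did while IKKb was inhibited. The inhibitor was given for 3 h of 2 days and for 24 h of 3 days of doxycycline. These ratios can therefore also hold changes made while IKKb was active. Here 164 genes passed, 109 lower and 55 higher, with 1014 at an unadjusted p under 0.05. Both groups shared 1 estimate of the spread, although log ratios of genes were 1.49 times wider on the inhibitor arrays. The width across genes differed by day as well. Its median absolute deviation was 0.16 at 2 and 0.26 at 3 days without inhibitor, and 0.25 and 0.38 with it. After scaling to equal spread 166 genes passed with and 140 without inhibitor, so the counts of 164 and 0 depend on this spread. In the likely direction MATR3 fell most (turned, it would have risen most), by a log2 mean of -2.06 ± 0.37 (SD, n = 2), 4.16-fold, followed by THOC2, an mRNA export factor, at -2.03 ± 0.90, the deubiquitinase USP25 at -1.81 ± 0.44 and NMD3 at -1.80 ± 0.22 (adjusted p 0.00781, 0.0237, 0.00781 and 0.0088). CD2AP (-1.79), DHX15 (-1.73), SEL1L (-1.67), OXSR1 (-1.55), WDR44 (-1.55) and HSP90B1 (-1.52) followed. MATR3, THOC2, USP25, NMD3, DHX15, SEL1L and OXSR1 rested on 1 probe each. Among called genes, in the same direction, IL23A, the p19 subunit of interleukin 23, rose most, at 1.15 ± 0.03, 2.21-fold (adjusted p = 0.0135), while DNAJC27 (1.81, adjusted p = 0.0602) and DGKG (1.17, 0.0521) had higher means and did not pass. ZNF83 (1.05), PRKACG (1.04), the histone methyltransferase DOT1L (0.99), SELENOO (0.98), PLXNB1 (0.88), ZNF440 (0.87), PF4 (0.84), ST3GAL1 (0.83) and MGAT4A (0.83) also rose. By size, 86 genes were lower and 30 higher beyond 1.5-fold on both arrays, and 6 were beyond it in opposite directions.

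Of the 52 measured NF-kB targets, 6 fell with inhibitor and none rose, and 43 had means below 0. They were CCR7, a homing receptor (-0.97 ± 0.35), TNFAIP3, which encodes A20, a feedback inhibitor of NF-kB (-0.88 ± 0.35), NFKBIA (-0.83 ± 0.07), IRF4 (-0.70 ± 0.23), and the NF-kB subunits NFKB1 (-0.73 ± 0.12) and REL (-0.62 ± 0.12). NFKB1 and REL are named because they passed, after their values were seen. All 5 NFKBIA probes and 5 of 6 TNFAIP3 probes were below 0 on all 4 arrays, while CCR7 rested on 1 probe. Adjusted over the list alone, 10 members fell. The list median was -0.19 (camera adjusted p = 0.0021; adjusted p = 0.684 with an estimated correlation). The list call ended without the 3 h inhibitor array (median -0.14, adjusted p = 0.0715). Without either array of doxycycline alone, which leaves 1 residual degree of freedom, the 6 genes had adjusted p-values of 0.053 to 0.0795 and none was called, and without the 24 h array REL (0.109) and IRF4 (0.105) were not.

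Of 20 measured IKK and NF-kB pathway components 4 fell: CHUK, TAB2, an adaptor of the TAK1 kinase upstream of IKK (-1.13 ± 0.07), TNFRSF13C, the BAFF receptor (-0.83 ± 0.13), and CYLD, a deubiquitinase that restrains the pathway (-0.67 ± 0.01). TNFRSF13C was named after its value was seen. TAB2, TNFRSF13C and CYLD rested on 1 probe each. Without either array of doxycycline alone CHUK and TAB2 kept their calls, while TNFRSF13C and CYLD did not. The remaining 16 did not pass and the list median was -0.05 (camera adjusted p = 0.219). ABC lymphoma markers had a median of -0.26, with 19 of 22 below 0 and 4 that fell: IRF4, CYB5R2 (-0.66), STAT3 (-0.65) and the kinase PIM2 (-0.56), with a camera adjusted p of 0.00103 that became 0.684 with an estimated correlation. The calls of these 4 genes did not hold without either array of doxycycline alone, nor without the 24 h array, and CYB5R2 rested on 1 probe. GCB lymphoma markers lay on the other side of 0, at 0.18 (adjusted p = 0.0401, and 0.684), with 15 of 18 above 0 and none called. Among them ASB13 stood at 0.60 and SERPINA9 at 0.43, the latter with 0.16 on the 3 h and 0.70 on the 24 h array. The GCB median was 0.04 on the 3 h array and 0.34 on the 24 h array, so it rested mostly on the latter. On these arrays 44.2% of the GCB probes and 14.4% of the ABC probes lacked a value on 1 or more of the 4 arrays.

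MYC and ribosome biogenesis genes had the lowest median of the 20 lists with inhibitor, -0.49, with 16 of 17 below 0, none called over all genes and 10 that fell when adjusted over the list alone (camera adjusted p = 0.000975). NCL stood at -0.94, ENO1 at -0.82 and NOP56 at -0.75. Cell cycle genes had -0.28 (0.000975), and 2 of 38 fell, MCM4 (-1.14 ± 0.27) and the spindle checkpoint kinase BUB1B (-0.75 ± 0.35). The unfolded protein list had -0.22 (0.0401), and HSP90B1 was its 1 called member of 20. Housekeeping genes had -0.31 (0.0216), with ACTB at -0.72. T cell markers lay at 0.11 (0.0425), where NKG7, a granule protein of cytotoxic cells, rose to 0.55 ± 0.01 as the 1 called member of 14. BUB1B and NKG7 lost their calls without either array of doxycycline alone and without the 24 h array, while MCM4 and HSP90B1 kept theirs. MCM4 and NKG7 rested on 1 probe each. With an estimated correlation each of these lists had an adjusted p of 0.684. The estimates stated above for cell cycle, MYC, unfolded protein and housekeeping genes hold here too, and so does the limit of 2 degrees of freedom.

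Leaving out either array of doxycycline alone gave 34 called genes (2 higher, 32 lower) in place of 164, and leaving out the 3 h inhibitor array gave 858 (431 higher, 427 lower). Of 40 called genes followed through the alternatives, taken by the naming rule or named because they passed, 14 were still called without either array of doxycycline alone and 30 without the 24 h array. With the doxycycline day as a block 908 passed, 402 higher and 506 lower.

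**Figure D2:**
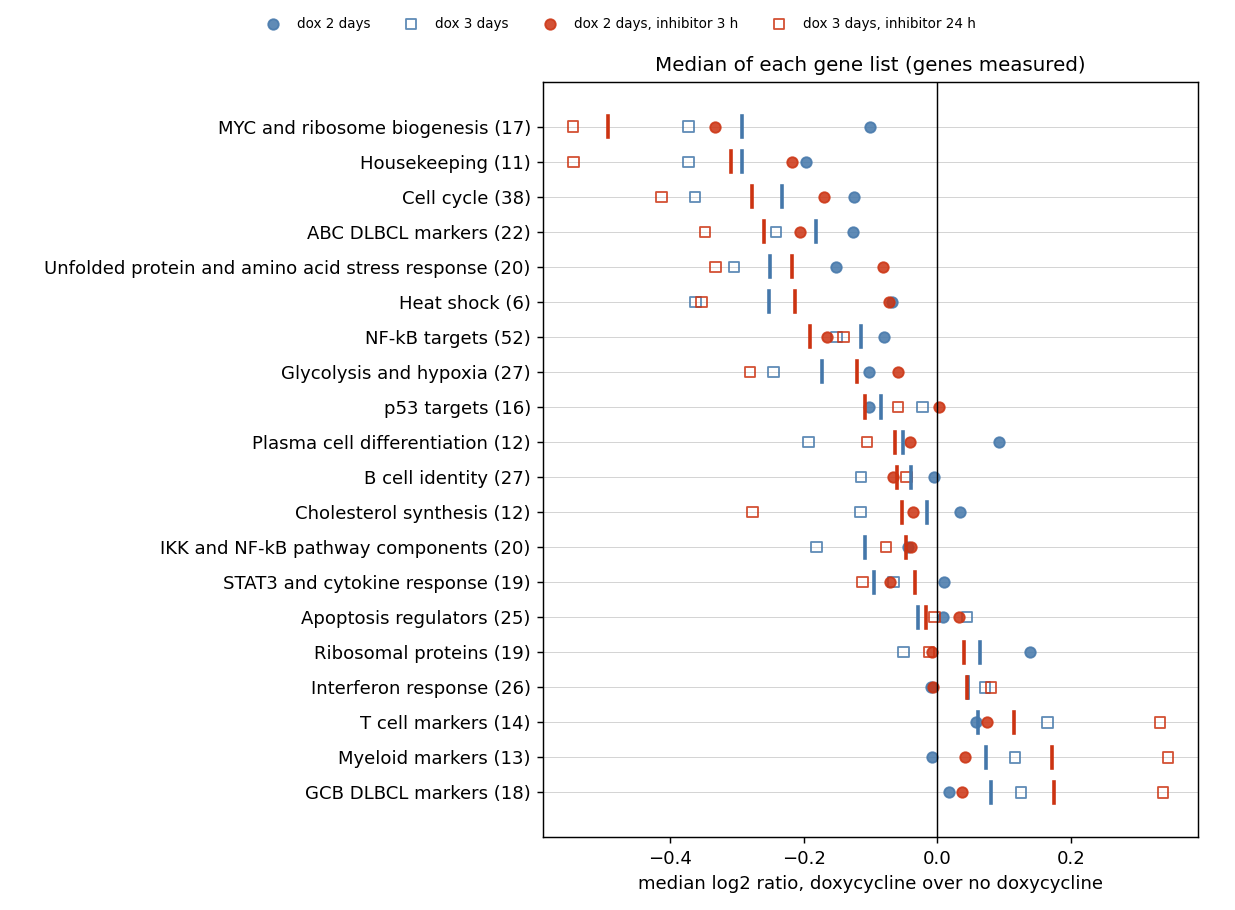
Median log2 ratio (horizontal axis, doxycycline over no doxycycline in the likely direction) of 20 gene lists on each array, with circles for 2 days and open squares for 3 days of doxycycline, blue without and red with inhibitor, and bars for the median of the members' group means. MYC and ribosome biogenesis genes lie lowest with inhibitor, at -0.49, and GCB lymphoma markers highest, at 0.18.

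The difference between the groups asks whether the hairpin's effect changed when IKKb was inhibited. A constant dye bias of a probe cancels in this contrast. The 8 NF-kB targets that differed most were CXCL10 (-0.60), TNFAIP3 (-0.55), NFKBIA (-0.54), CFLAR (-0.50) and CCR7 (-0.45), lower with inhibitor, and RGS1 (0.55), STAT5A (0.53) and CCL22 (0.53), higher with it. NFKBIA went from -0.19 and -0.40 on the arrays without inhibitor to -0.78 and -0.88 on those with it, and TNFAIP3 from -0.22 and -0.44 to -0.63 and -1.13. STAT5A with inhibitor rested on the 24 h array (0.63), as the 3 h array had -0.04, and so did RGS1 (0.75 and 0.04). CCR7 differed by 0.08 at 2 days and by -0.97 at 3 days. None of the 8 passed by itself (adjusted p = 0.989 for each but CCR7, at 0.999).

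The NF-kB list as a whole was lower with inhibitor, by a median of -0.08, with 33 of 52 members below 0 (camera adjusted p = 0.0161). Without the 24 h inhibitor array the list's median was -0.09. The call held with the doxycycline day as a block (camera adjusted p = 0.0106). It held on single probes too (0.000167), a test that counts several probes of a gene. This call was lost with an estimated correlation (adjusted p = 0.993), after scaling to equal spread (median -0.05, adjusted p = 0.208), and with probes measured on at least 1 array per group (0.204). It was also lost without the array of 3 days of doxycycline alone (median -0.13, adjusted p = 0.0739) and without the 3 h inhibitor array (median -0.02, adjusted p = 0.214). Without the 2-day array of doxycycline alone it kept an adjusted p of 0.03 with a median of -0.03.

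Among the fixed NF-kB genes and cytokines, BCL2A1, an anti-apoptotic gene, had means of 0.21 without and -0.16 with inhibitor, and all 5 of its probes were lower with it. CCL4 had -0.03 and 0.32, CCL3 0.07 and -0.01, IL6 -0.13 and -0.27, IL10 -0.04 and -0.02 and CD44 -0.16 and -0.22. Of 3 probes each, 2 of IL6 and 2 of CCL3 were higher with inhibitor, against the sign of the gene's mean difference. None passed, and the differences of CCL3, IL10 and CD44 changed sign when single arrays were left out. BIRC3 was not measured on all 4 arrays.

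ABC lymphoma markers differed by a median of -0.12 (16 of 22 below 0, camera adjusted p = 0.0161), with CCND2 at -0.42, PIM2 and CYB5R2 at -0.40 and RHOF at -0.29. CCND2, PTPN1, IRF4, BATF, CD44 and PIM1, each with a difference below 0, are also on the NF-kB list, so these lists are not independent. MYC and ribosome biogenesis genes differed by -0.15 (14 of 17, adjusted p = 0.0257), with MYC at -0.37 and NCL at -0.33, and NCL's sign turned without the 24 h array. Both had an adjusted p of 0.993 with an estimated correlation. CHUK and CYLD of the pathway list differed by -0.42 and -0.49, and IKBKG and BCL10 by 0.38 and 0.40, BCL10 mainly on the 24 h array. That list had 10 members above and 10 below 0 (median 0.02). The other 17 lists did not pass.

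Over all genes limma called 0 for the difference (smallest adjusted p 0.989), with 173 at an unadjusted p under 0.05 where chance gives 179. The largest positive differences included DNAJC27 (1.59), BCAS4 (1.27), IL23A (1.02), DGKG (1.00) and ST3GAL1 (0.99), and the largest negative ones THOC2 (-1.08), ETV3, a transcriptional repressor (-1.06), the B-cell chemokine CXCL13 (-1.05), NOC3L (-1.03) and USP25 (-0.92). Several rested on single arrays: leaving out 1 array moved DNAJC27 from 0.46 to 2.72, BCAS4 from 0.30 to 2.25, DGKG from 0.45 to 1.55, THOC2 from -1.71 to -0.44, NOC3L from -1.61 to -0.44 and CXCL13 from -1.60 to -0.50. DNAJC27 had 2.94 on the 24 h array and 0.69 on that of 3 h, and BCAS4 -1.85 on the 3-day array without inhibitor and 0.10 at 2 days. THOC2 differed by -0.10 at 2 days and by -2.06 at 3 days. The range was narrower for IL23A (0.81 to 1.23) and ST3GAL1 (0.68 to 1.30). The count rose to 119 without the 3 h inhibitor array and to 10 without that of 24 h, which compare a single array with 2. With probes measured on at least 1 array per group 4 genes passed.

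**Figure D3:**
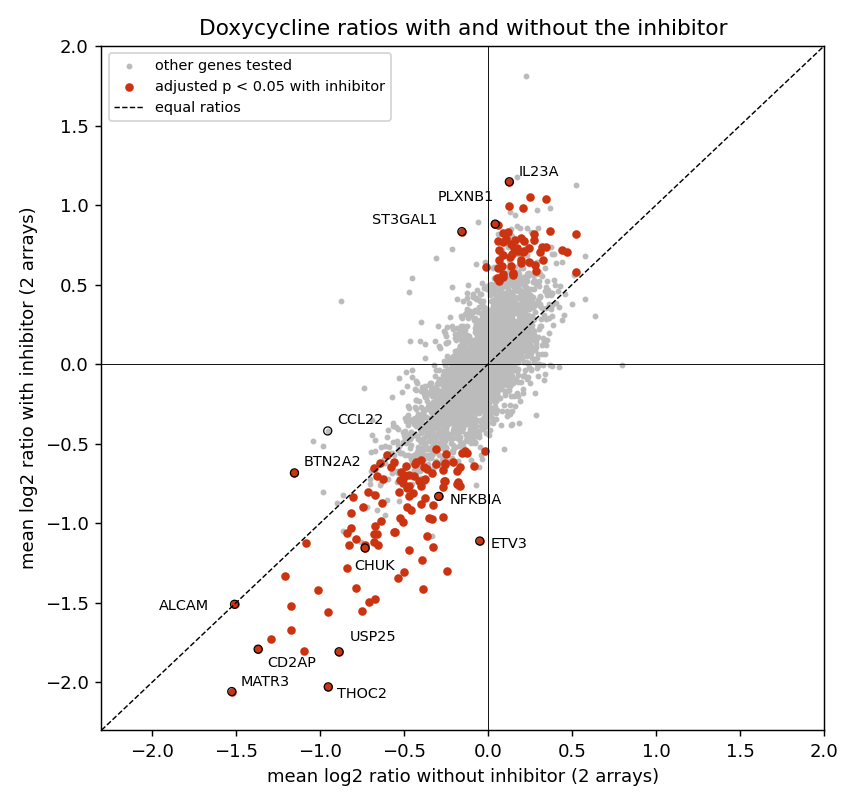
Mean log2 ratio with inhibitor (vertical axis, 2 arrays) against that without it (horizontal axis, 2 arrays) for 3589 genes, with the 164 genes called with inhibitor in red, named genes circled and a dashed line where both are equal. MATR3 lies at -1.52 and -2.06, and IL23A at 0.13 and 1.15.

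Genes called with inhibitor mostly lay on the same side of 0 without it. Of the 164, which were chosen on the arrays with inhibitor, 162 had the same sign of the mean on those without it, against 77.9% of all genes. Across genes, which are not independent replicates, the Pearson correlation was 0.47 between the arrays without inhibitor and 0.60 between those with it, and 0.75 between both arrays of 3 days, against 0.53 between both of 2 days and 0.48 and 0.51 between the other pairs. In total 24 genes were beyond 1.5-fold lower on all 4 arrays in the likely direction, CHUK and TAB2 among them, and none was beyond 1.5-fold higher (turned, 24 higher and none lower). Each of these arrays used the same dye order, so a bias of single probes would also recur on all of them.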

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

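The test of wider log ratios and the test of a shift on 1 day were chosen after their results were seen, and the bound of the latter was made stricter after that.

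The NF-kB target list stood out because its effect differed between the groups in a test of the difference itself, with a median of -0.0847 with minus without inhibitor (camera adjusted p = 0.0161), a call lost with an estimated correlation (0.993) and with fry (0.953). A shift confined to 1 day cannot be told apart: the list lay below all of 10000 random lists at 2 days (median -0.154, 32 of 52 members below 0) and at their 0.63 percentile at 3 days, but there only 28 members were below 0 (median -0.0442, all genes 0.0515), and without the 3 h array the call ended (median -0.0217, adjusted p = 0.214). Wider log ratios on the inhibitor arrays stay open, since scaling all arrays to equal spread left a median of -0.0528 and an adjusted p of 0.208, and so does a stronger knockdown of CHUK on them, since the means with inhibitor minus 1.58 times those without, the ratio for CHUK, left a median of -0.0164 and an adjusted p of 0.497. The outcome of both depends on the scale taken: with the slope over all genes, 1.15, which noise in the means lowers and which lies below the ratio of spreads, 1.49, the list kept a median of -0.0767 and an adjusted p of 0.0418. CHUK itself differed by -0.71 at 2 days and by -0.14 at 3 days, and its difference did not pass. Its ratio of 1.58 thus rests mostly on the 2-day arrays. The biological explanation that the design names, a larger need for IKKa while IKKb is inhibited, stays open too and was not tested, since these arrays do not separate it from the others.

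In the same test ABC lymphoma markers differed by a median of -0.116 (adjusted p = 0.0161) and MYC and ribosome biogenesis genes by -0.1473 (0.0257), which likewise did not hold with an estimated correlation (0.993 for each). The ABC list shares members with the NF-kB list.

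Of 150 genes named by rule, 9 had both arrays of one group above 0 and both of the other below 0. Below 0 without and above 0 with inhibitor were WASF3 (difference 0.9937), GPSM3 (0.9765), PRMT2 (0.9205), ADM (0.7025), AEN (0.596), RGS1 (0.5477) and TP53INP1 (0.5015). The reverse held for BCL2A1 (-0.3656) and IL21R (-0.2739). The signs themselves were not tested, and limma's test of each gene's difference did not pass (adjusted p 0.989 to 0.999). Over all 3589 genes 171, or 4.76%, had this pattern, where independent signs give 12.5%.

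Outside the genes, 2992 probes without a gene name were measured on all 4 arrays. Tested as single probes with limma, 263 of them passed with inhibitor, 145 lower and 118 higher, against 6 without inhibitor and 0 for the difference. Over all 9788 probes of that fit 979 passed with inhibitor and 24 without, so probes without a name were not called more often than the rest.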

How the results depend on the processing

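The arrays give ratios only, so signal over background is unknown, and each group is a pair of time points. Median centring changed none of the 3 NF-kB list calls, and centring and a robust prior gave 160 and 164 genes with inhibitor. With inhibitor, scaling gave 166 genes and probes with a value on 1 array per group gave 188 (95 higher, 93 lower). Of 160 gene results, taken by the naming rule or named because they passed, each for 1 comparison, 40 were called. Centring, the robust prior and the day block kept all 40, scaling kept 33, with 37 gained under the block and 30 under scaling, and the wider choice of probes kept 36.

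Scaling to equal spread gave 140 genes without inhibitor, and the NF-kB list had -0.1286 there and a difference of -0.0528, neither past the threshold. Probes with a value on 1 array per group gave 4 genes for the difference, -0.0817 for the list (not past) and a reversed IL10 difference of -0.0165. Single probes gave 24 calls without and 979 with inhibitor, partly because more items were tested. An adjusted p under 0.10 gave 6 and 590. With the estimated correlation and with fry the NF-kB list kept its medians of -0.1136, -0.1909 and -0.0847 and lost all 3 calls. The fry adjusted p was 0.35, 0.168 and 0.953. The 2-fold rule gave 4 genes without and 20 with inhibitor, and single probes at 1.5-fold gave 127 and 419. Except where the construction shows it, the cause was not tested.

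The labels number no replicates, so arrays were paired only by doxycycline day. As a block it gave 56 genes without and 908 with inhibitor, and it ended the NF-kB call without inhibitor (-0.1136). The change from 2 to 3 days correlated between the groups at r = 0.45 across genes.

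Leaving out each array in turn assumes that the lone array of a group varies like the other group. Counts ranged from 0 to 231 without inhibitor, from 34 to 858 with it, and from 0 to 119 for the difference. The 231 came without either inhibitor array, the 34 without either array of doxycycline alone, and the 858 and 119 without the 3 h inhibitor array. The NF-kB median ranged from -0.1503 to -0.0792 without inhibitor, from -0.1909 to -0.1403 with it, and from -0.1259 to -0.0217 for the difference. Single genes reversed, none of them called. Differences ranged from -1.8095 to 0.1995 for XAF1, -0.72 to 0.06 for NCL, -0.645 to 0.0485 for NOP56, -0.4252 to 0.0562 for NOP2, -0.2895 to 0.1195 for CCL3, -0.053 to 0.089 for IL10 and -0.2156 to 0.0954 for CD44. STAT5A with inhibitor ranged from -0.035 to 0.634 and MAML3 without inhibitor from -0.039 to 0.742. The cause was not tested.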

Other observations

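The test of long genes was chosen after the correlation of ratio and span across genes (-0.05) was seen. It replaced a first form, based on a trend of ratio with span, whose outcome had also been seen.

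Gene groups that did not pass as lists still held single called genes with inhibitor. Of 19 STAT3 and cytokine response genes (median -0.03) 3 fell: IL2RG, the common gamma chain of cytokine receptors, at -0.71 ± 0.15, STAT3 and PIM2. BIK, a pro-apoptotic gene, rose to 0.62 ± 0.09 as the 1 called member of 25 apoptosis regulators (median -0.02). STARD4, a sterol transfer protein, fell to -0.76 ± 0.36 among 12 cholesterol synthesis genes (median -0.05). CEBPD, a transcription factor of myeloid cells, rose to 0.71 ± 0.18 among 13 myeloid markers (median 0.17, camera adjusted p = 0.099). Of 12 plasma cell genes (median -0.06) HSP90B1 and IRF4 fell. BIK is named because it passed, while IL2RG, STARD4 and CEBPD fell under the naming rule. Without either array of doxycycline alone IL2RG, STAT3, PIM2, BIK, STARD4, CEBPD and IRF4 were not called. Without the 24 h array STAT3, PIM2, BIK, STARD4 and IRF4 were not. CEBPD rested on 1 probe.

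No member was called among the other lists, whose medians with inhibitor were -0.21 for 6 heat shock genes, -0.12 for glycolysis and hypoxia, -0.11 for p53 targets, -0.06 for B cell identity, 0.04 for interferon response and 0.04 for ribosomal proteins. Without inhibitor these medians were -0.25, -0.17, -0.08, -0.04, 0.05 and 0.06, of which glycolysis and hypoxia passed (adjusted p = 0.0446, and 0.627 with an estimated correlation). Median, mean and camera direction differed in sign for ribosomal proteins in both groups (means -0.02 and -0.03, direction up), for apoptosis regulators in both groups, for p53 targets with inhibitor, and for several lists in the difference, none of which passed. Fry's test for change in either direction passed with inhibitor for IKK pathway components, STAT3 response, ribosomal proteins and p53 targets (adjusted p = 0.0406 each), and without inhibitor for ribosomal proteins (0.0192).

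A group of 24 genes was beyond 1.5-fold lower on all 4 arrays, with CHUK, MATR3 and CD2AP among them, and the 4 that had 2 or more probes used here had all 9 of these below 0 on every array. The genes were chosen on the mean of these same probes, so their agreement is no separate support. The 24 genes were longer (median span 59.9 kb, against 33.9 kb for all genes), with a median over the 4 arrays of -1.16. But 433 genes of like span, 5 of them among the 24, had a median of -0.03 (95% of them between -0.69 and 0.36). Most genes of like span were thus not 1.5-fold lower, which argues only against a long span being enough by itself. Because the 24 were chosen for low ratios, their distance from the genes of like span is no separate support. A dye bias of single probes stays open. The 6 left-out probes of these genes, from 4 genes, had a median of 0.0325 (interval -0.60 to 0.35, 2 of 6 below 0), too few to decide, beside 0.12 for left-out probes of all genes. Unintended targets of the hairpin and effects of doxycycline were not tested, since no control hairpin was analysed here.

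The 55 genes that rose with inhibitor may in part be dim spots whose ratios lie above 0, a hypothesis that came from the data. Of their probes 35.5% lacked a value on 1 or more arrays, against 22.3% for the other tested genes, a ratio of 1.59 (95% bootstrap interval 1.24 to 1.92), and 22.2% for the genes that fell. Named probes lacking a value had a median ratio of 0.16 with inhibitor, against -0.03 for complete ones. Across the 20 lists the share of such probes correlated with the list median with inhibitor (Spearman 0.62, Pearson 0.66) and without it (0.45 and 0.56). T cell markers had 60%, MYC genes 10% (median -0.49 with inhibitor) and housekeeping genes 0% (-0.31), though ribosomal proteins had 8.2% and 0.04. The relation thus covers lists below 0 too and is not confined to the genes that rose. Missing values stand in for dimness here, no signal was used, and no biological explanation was tested.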
